A study of Mus musculus with 16 samples.

How the data were processed

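The scanner files gave, per the file headers, raw spot and local background intensity in each channel, written by the Agilent Feature Extraction software in versions 9.1.1.1, 9.1.3.1 and 9.5.1.1. The same files hold a log10 ratio of red over green, per the file headers made by spatial detrending, background subtraction and lowess dye normalization. The deposited series table holds a single log2 ratio per array, centred near 0, for which the authors' processing notes name limma without a version or the step it was used in. Intensity was the unit analysed, and the other units served as alternatives. Per the labels' protocols, 100 ng of total RNA were amplified and labelled with Cy3 or Cy5, and each sample was hybridised in both dye orientations against the pooled cell line reference. Parts of the methods beyond this are not given in the sources used here.

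The columns of the series table were compared with the scanner files. Of 16 columns 6 matched best the array they are labelled with and 10 another array, and 8 had the opposite sign of the array they matched, with absolute correlations of 0.944 to 0.996 to the best match. In the table as labelled the 2 columns of a sample, which should hold the same RNA, differed by up to 6.06 log2 (median over the 3 called kappa units). The 2 arrays of a sample in the scanner files differed by under 2 in every sample. The scanner files' own attribution was used for every result in the report, and the table was used as labelled and with its columns rematched as alternatives only. In the table the columns labelled Auto.Pos sample 1 match WT sample 1, and those labelled WT sample 1 match WT sample 2. Those labelled WT sample 2 match Auto.Neg sample 1. Values read by its labels for Auto.Pos, Auto.Neg and WT therefore mix these groups. The table has 0 columns that belong to no sample.

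The work was done in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Mean foreground was corrected for median background with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0. Outlier spots were dropped. A probe was kept where the sample channel was well above background, by the scanner software's own mark, on both arrays of at least 2 of the 8 samples, which left 29640 of 41174 probes. Log ratios were turned to sample over reference, and the 2 arrays of a sample were averaged, with 356 gene-by-sample values resting on 1 array and 6 genes lacking a sample. Each gene was represented by its probe of highest mean intensity, and the value of another kept probe is printed for named genes where it was less than 50% of the printed difference or had the other sign. Probes were named by accession (22951), by the name in the file (8455), by symbol (6659) or by synonym (3109), and coordinates are those of the files (mm7).

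limma was fitted to the 8 samples with 1 mean per group, 3 residual degrees of freedom among samples and 2.11 prior degrees of freedom. Auto.Pos, Auto.Neg and WT were compared pairwise, p-values were adjusted over all tested genes by the method of Benjamini and Hochberg, and genes at an adjusted p under 0.05 were called. A second threshold of 0.1 was counted. Edited and Non-edited, with 1 sample each, were compared by genes at least 2-fold apart in both dye orientations, and by limma with the spread of the replicated groups, which assumes that the lone samples vary like them. Values within slide 2 and scan day 3 are single differences with no test. The wording "well above background" refers to the scanner software's mark throughout, and "called" means past the adjusted threshold.

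There were 25 gene lists written from general knowledge. They covered the B cell receptor complex, inhibitors of receptor signalling, NF-kB, activation-induced genes, MYC-related genes, the cell cycle, survival and death, NOD and inflammasome receptors, Toll-like receptors, the interferon response, antigen presentation and heat shock genes. Others covered follicular, marginal zone, B-1, transitional, germinal centre and plasma cells, and T cells, NK cells, macrophages, dendritic cells, neutrophils, erythroid cells and sex-linked genes. A name rule for immunoglobulin genes and the genes within 10 Mb of Thy1 brought the number to 27. Lists were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 27 lists, and the wider immunoglobulin lists were adjusted among themselves. For each list the genes called over all genes were counted, and those called when p-values were adjusted over the list alone. List medians of Edited against Non-edited were placed among those of 10000 random lists.

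The sample groups, comparisons, thresholds and most alternatives were chosen before the data were examined. The wider immunoglobulin rule, the genes near Nod1, the rematched series table, the scanner block, the fit without slide 2, the sets of 100 ranked genes and the added named genes were chosen after seeing the data. Genes were named by a rule: Nod1, Nod2, Ripk2 and Thy1 always, the 8 highest and 8 lowest called genes with a name, up to 3 members of a list past the threshold and up to 2 more members as values, and the 6 highest and 6 lowest for Edited against Non-edited. Because the only called genes were kappa units without a symbol, these and the 8 highest and 8 lowest genes at least 2-fold apart in all 4 pairs of samples were added after the values were seen.

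The pipeline was tested on simulated data made from the Auto.Pos and Auto.Neg comparison with 20469 genes, from the turning of log ratios to sample over reference onward. Of genes given a 2-fold change 0 of 67 were called by limma and 64.2% had an unadjusted p under 0.05, of 4-fold changes 26 of 67 (38.8%) were called, and of 16-fold changes 49 of 66 (74.2%). Of 20248 unchanged genes 3 were called. A list of 21 genes, the interferon response, shifted by 0.5 log2 was called by camera, and 0 unshifted lists were. Noise was drawn independently for each gene, without slide effects, while in the data this list had an estimated correlation of 0.586. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes.

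Alternatives covered background correction, normalization, the scanner software's ratios, the series table, the probe filter, outlier spots, the gene unit, the variance model, the 16 single arrays, the samples in the fit, blocks for protocol, scanner and sample number, each dye alone, each sample left out and the thresholds. No genome sequence was used, so probe sequences were not aligned. Transcripts of the transgenes were not separated from those of other immunoglobulin genes.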

Results

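Gene expression was measured in follicular B cells, the mature recirculating B cells of the follicles, from C.B17 mice on dual-colour Agilent mouse arrays. The 16 arrays held 8 biological samples, each hybridised as a dye-swap pair of 2 arrays against a common reference RNA pooled from 6 cell lines. The Auto.Neg group (n = 2) carried a transgenic receptor against the thymocyte antigen Thy-1 (VH3609µ/Vk21-5κ) in mice lacking Thy-1. The Auto.Pos group (n = 2) carried a transgenic receptor against intestinal goblet cells (VH3609µ/Vk19-17κ, although a further label field writes the light chain as Vkappa17-17kappa), and the WT group (n = 2) was wild type. Non-edited and Edited cells (n = 1 each) came from Thy-1 knockout mice with 1 copy each of the VH3609 and Vk21-5 transgenes, and editing is the usual term for the replacement of a receptor chain by a further gene rearrangement. All values are log2 ratios of sample over reference, with the arrays of a pair averaged, and differences between groups are on that scale unless a fold is named. The p-values measure only the spread between these samples, since the labels do not say whether 2 samples of a group came from separate mice. The number of samples limits the precision.

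The sample channel was well above background for 66.6% to 75.7% of probes on the Auto.Neg arrays, 66.6% to 71.0% on the Auto.Pos arrays and 64.7% to 81.9% on the WT arrays. The shares were 61.9% and 64.0% for Non-edited and 66.0% and 66.2% for Edited. The median signal per array ran from 101.5 to 735 in Cy3 and from 92.2 to 1039 in Cy5, and 0 probes were saturated. The arrays of 1 sample, turned to the same direction, correlated at 0.810 to 0.936 across probes. After the filter on dim probes, 20469 genes were tested.

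The samples did not sort by group alone. The arrays lay on 7 slides scanned on 4 days, and only slide 2 held samples of 2 replicated groups, namely Auto.Neg sample 2 and Auto.Pos sample 1. These correlated at 0.978 across genes, above the 0.903 between the Auto.Neg samples, the 0.904 between the Auto.Pos samples and the 0.923 between the WT samples. Genes are not independent replicates, so these correlations carry no p-value. Auto.Pos sample 2 and WT sample 2 shared scan day 3, and no slide or scan day held both Auto.Neg and WT. The differences inside slide 2 and inside scan day 3, each from 1 sample per group, are therefore printed beside the group differences.

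**Figure D1:**
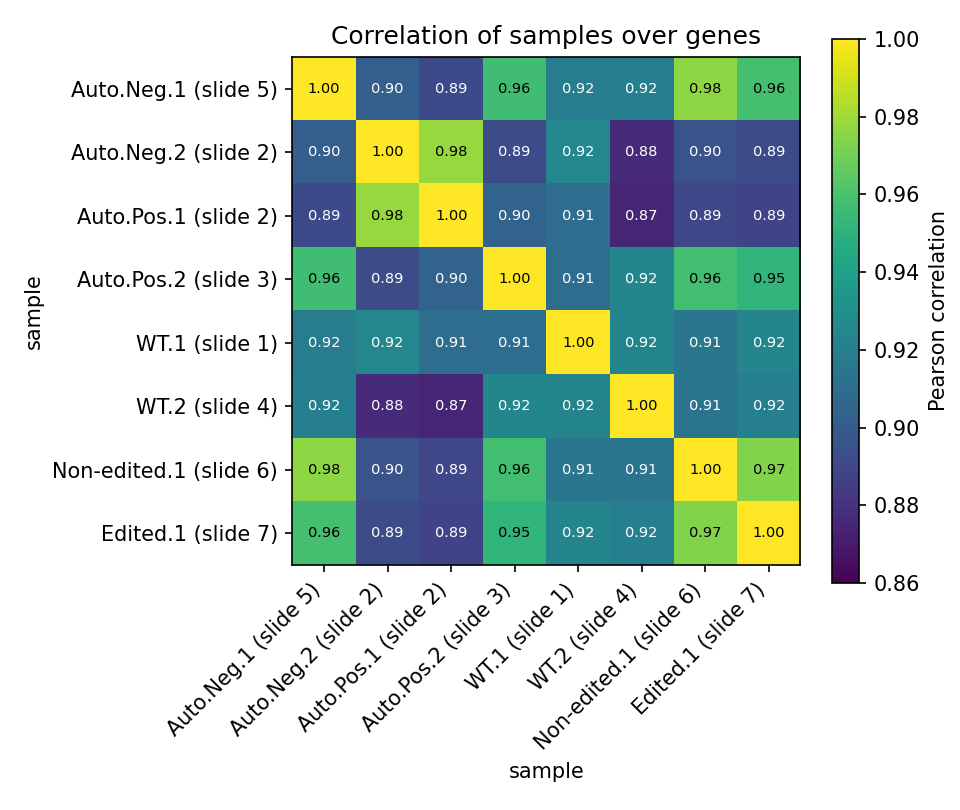
Pearson correlations of log2 ratios across 20469 genes between the 8 biological samples, as a heatmap with samples on both axes and colour for the correlation. The samples of slide 2, Auto.Neg 2 and Auto.Pos 1, correlate at 0.978, and each lies closer to the other than to the second sample of its own group (0.903 and 0.904).

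Thy1, the gene knocked out in the Auto.Neg, Non-edited and Edited mice, encodes a surface glycoprotein of thymocytes and T cells and had 2 probes on chromosome 9. The brighter probe (mm7 coordinates 43982862 to 43982921) read -4.00 and -4.19 in Auto.Neg, -3.73 and -4.22 in Auto.Pos, -4.31 and -4.54 in WT, -3.97 in Non-edited and -4.03 in Edited. The other probe (43981253 to 43981698) read -0.55 and 0.46 in Auto.Neg, -0.52 in Non-edited and -1.43 in Edited. It read -2.93 and -3.77 in Auto.Pos and -3.62 and -3.06 in WT, so all 4 knockout samples lay above all 4 others on this probe. The sources used here do not give the deleted part of the gene, so neither probe checks the genotype. Follicular B cells carry little Thy1, and both probes read below the reference in 7 or more of the 8 samples. Each probe was nonetheless well above background on all 16 arrays, so these ratios do not show that the signal was low.

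The comparison of Auto.Pos with Auto.Neg cells addresses the series' question of what differs in B cells whose receptor meets its antigen. The groups also differ in their transgenic light chain, which is Vk21-5 in Auto.Neg only. Further differences are the antigen of the receptor and the Thy-1 knockout, given for Auto.Neg alone. Xist read 0.02 and 9.12 in Auto.Pos against 0.16 and 0.02 in Auto.Neg. These differences cannot be told apart from antigen contact here. In the main fit the only genes past the threshold were 3 kappa light chain units, which fell. These units read higher in the Vk21-5 samples than in WT. Their calls can follow from the light chain the mice were given and cannot be read as an effect of antigen contact. Nod1, the intracellular receptor for peptidoglycan fragments that the series is named for, lay 4.60-fold higher in Auto.Pos without passing the threshold over all genes. Cd9, a tetraspanin typical of marginal zone and B-1 cells, lay 6.22-fold higher, likewise short of the threshold. At a preset correlation between genes, marginal zone B cell markers shifted up as a list, and NF-kB target genes, germinal centre markers, interferon response genes and sex-linked genes shifted down. With an estimated correlation none of these shifts passed (adjusted p = 0.517, 0.517, 0.626, 0.998 and 0.517, in this order).

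In this comparison limma called 3 of 20469 genes, 0 higher and 3 lower in Auto.Pos, and 213 genes had an unadjusted p under 0.05. All 3 are kappa light chain units without a gene symbol, named here after their values were seen. All 3 also read higher in the Vk21-5 samples than in WT. ENSMUST00000089814, described in the files as similar to an Ig kappa V-III region and lying on chromosome 6 from 70591160 to 70591219, fell by 7.34 (SE 0.298, limma adjusted p = 0.0231). It read 6.69 and 7.24 in Auto.Neg, -0.50 and -0.24 in Auto.Pos, 4.14 and 3.67 in WT, 6.95 in Non-edited and 5.995 in Edited, and the difference on slide 2 was -7.74. BC080787, on chromosome 6 from 70625849 to 70625908, fell by 5.73 (SE 0.247, limma adjusted p = 0.0231), with -5.91 on slide 2. ENSMUST00000089809 fell by 4.93 (SE 0.238, limma adjusted p = 0.0272), with -5.19 on slide 2. Each replicated group held 1 sample of each scanner protocol. With protocol as a block limma gave 554 genes at an unadjusted p under 0.05 and called 6, of which 3 were higher in Auto.Pos. The 3 kappa units each had an adjusted p of 0.0391 in that fit. Over all alternatives their adjusted p ran from 7.3e-06 (ENSMUST00000089814) and 0.00143 (ENSMUST00000089809) up to 1.00, with the lowest for BC080787 between these. Leaving out any 1 of the 6 replicated samples left 0 calls by limma, with 135 to 445 genes at an unadjusted p under 0.05, while the differences stayed at -7.61 to -7.06, -5.84 to -5.63 and -5.18 to -4.68.

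Nod1 had 1 probe, named Card4 in the files, on chromosome 6 from 54887383 to 54887442. It read 2.89 and 3.23 in Auto.Neg (mean 3.06, SD 0.240), 5.45 and 5.08 in Auto.Pos (mean 5.26, SD 0.264) and 4.04 and 3.66 in WT (mean 3.85, SD 0.267). The difference of Auto.Pos and Auto.Neg was 2.20 (SE 0.263, limma adjusted p = 0.485 over all genes and 0.00787 adjusted over the list alone). It was 2.22 on slide 2, and the adjusted p was 0.15 with the protocol block and 0.0453 to 1.00 over all alternatives. In the submitters' table read by its labels the Nod1 difference was 0.147, with the columns labelled Auto.Pos sample 1 matching WT sample 1. Nod2, the sister receptor, read 0.95 and 1.03 in Auto.Neg and -0.01 and 0.81 in Auto.Pos, a difference of -0.59 (SE 0.320), with -1.05 on slide 2. Ripk2, the kinase both receptors signal through, differed by 0.04 (SE 0.403) and was well above background on 13 of the 16 arrays. Across the NOD and inflammasome list, 12 of 22 measured genes lay higher and 10 lower, with 0 called over all genes and 1, Nod1, adjusted over the list alone. The list's median difference was 0.03, turning to -0.08 under median centring, and its camera adjusted p was 0.912. Slc15a3, a transporter of bacterial peptides into the cytosol, differed by -0.89.

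**Figure D2:**
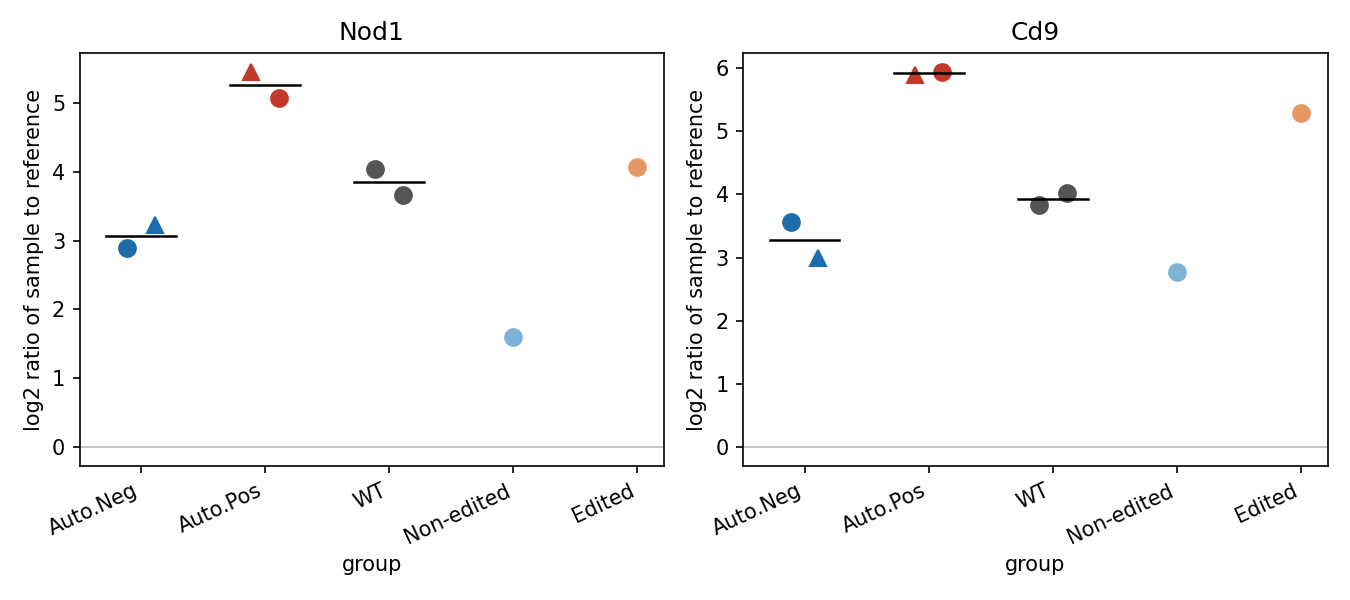
Log2 ratio of sample over reference for Nod1 (left) and Cd9 (right), with 1 point per biological sample, triangles for the samples of slide 2 and a line at each group mean. Nod1 lies at 5.45 and 5.08 in Auto.Pos against 2.89 and 3.23 in Auto.Neg, and at 4.07 in Edited against 1.60 in Non-edited, and Cd9 lies at 5.89 and 5.94 in Auto.Pos against 3.57 and 2.99 in Auto.Neg.

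Cd9 was the member of the marginal zone list that stood furthest from 0. It read 3.57 and 2.99 in Auto.Neg, 5.89 and 5.94 in Auto.Pos and 3.83 and 4.02 in WT. The difference of 2.64 (SE 0.258) had a limma adjusted p of 0.275 over all genes and 0.00202 adjusted over the list alone, with 2.90 on slide 2 and 1.08 on the second kept Cd9 probe. Tm6sf1 lay 0.75 higher. Of the 15 measured marginal zone genes, 11 lay higher and 4 lower (median 0.20, slide 2 median 0.28, -0.0766 without Auto.Pos sample 1), with 0 called over all genes and 1 adjusted over the list alone. The camera adjusted p was 0.0264, and the adjusted p = 0.517 with an estimated correlation.

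Genes at least 2-fold apart in all 4 pairs of samples at an unadjusted p under 0.05 were listed after the values were seen. They comprised 20 higher and 20 lower genes, of which 13 and 8 had gene names and were not immunoglobulin. The higher ones with the largest differences were the protease inhibitor genes Ctla2a (2.72, slide 2 4.09) and Ctla2b (2.57, slide 2 3.79), Cd9, the myosin light chain gene Myl9 (2.48, slide 2 3.67), Nod1 and Gchfr, a regulator of tetrahydrobiopterin synthesis (2.17, slide 2 1.85). Without 1 sample Ctla2a ran from 1.46 to 3.97, Ctla2b from 1.31 to 3.83 and Myl9 from 1.14 to 3.81. Gpat2, an acyltransferase of lipid synthesis, lay 2.10 higher (slide 2 1.48) and the lipoxygenase gene Alox12 1.99 higher (slide 2 2.66; 0.65 on another probe). The lowest were the Y-linked Eif2s3y (-6.01, slide 2 -5.70), the adhesion genes Dscam (-1.84, slide 2 -1.91; 0.08 on another probe) and Lrfn5 (-1.61, slide 2 -1.11), and Loxhd1 (-1.43, slide 2 -1.50), which was well above background on 2 of 4 Auto.Pos arrays. Parm1 (-1.39, slide 2 -1.51; 0.09 on another probe), the lymphocyte receptor gene Slamf1 (-1.38, slide 2 -1.16; -0.01 on another probe), Chst10 (-1.30, slide 2 -1.45) and the choline kinase gene Chka (-1.23, slide 2 -1.15; -0.47 on another probe) followed. The lowest limma adjusted p among these genes was 0.154, for Eif2s3y. Groups did not overlap for 3935 genes (19.2%), against 33.3% by chance if all 4 samples were exchangeable. They were not, since the deviations of Auto.Neg sample 2 and Auto.Pos sample 1 from their group means correlated at 0.788. Shared deviations lower this share, so 33.3% is not its value without a group difference.

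NF-kB subunits and target genes lay lower in Auto.Pos for 14 of 20 genes (median -0.18, slide 2 -0.18, without 1 sample -0.21 to -0.0411 with camera adjusted p up to 0.416), including Traf1, which is induced through NF-kB, at -0.67, while the kinase gene Chuk lay at 0.51 (-0.16 on another probe). The camera adjusted p was 0.0171, and the adjusted p = 0.517 with an estimated correlation. Germinal centre markers lay lower for 6 of 7 genes (median -0.44, slide 2 -0.19, without 1 sample -0.49 to -0.25 with camera adjusted p up to 0.196), with the death receptor gene Fas at -0.72 (0.13 on another probe) and Rgs13 at -0.47. Their camera adjusted p was 0.0112, and the adjusted p = 0.626 with an estimated correlation. Type I interferon response genes lay lower for 19 of 21 genes (median -0.30), with Rsad2 at -1.03 and Stat2 at -0.85 (-1.45 to -0.25 without 1 sample), yet the median was 0.45 on slide 2. Their camera adjusted p was 0.0114 and adjusted p = 0.998 with an estimated correlation, and without Auto.Neg sample 1 the list shifted up (median 0.29, camera adjusted p = 0.0199, against a range of 1.9e-10 to 0.998 over all alternatives). The samples compared differ in sex-linked genes within Auto.Pos, and the 4 measured ones shifted down (median -2.37, camera adjusted p = 0.00559), with adjusted p = 0.517 and an estimated correlation, and with 0.08 on slide 2. Without Auto.Pos sample 2 the list's median was -0.0343. The mean of Xist was 4.48 higher through Auto.Pos sample 2 alone (0.02 and 9.12 in Auto.Pos; 0.36 on another probe), while Eif2s3y differed by -6.01, and Eif2s3y alone passed adjusted over the list alone. The 3 units of the immunoglobulin name rule lay lower for 2 of 3 (median -0.61, slide 2 -0.50, camera adjusted p = 0.0478; without 1 sample -0.88 to -0.22 with 0.0503 to 0.512), with adjusted p = 0.552 and an estimated correlation. Each of these 5 lists had 0 genes called over all genes, and 0 adjusted over the list alone apart from Eif2s3y. In the submitters' series table read by its column labels, camera's direction turned for the NF-kB, interferon and immunoglobulin lists.

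The other lists did not pass camera in the main fit of this comparison. Activation-induced genes of B cells lay lower for 15 of 21 genes (median -0.13, camera adjusted p = 0.0513). Among them Egr2 differed by -0.77 (-1.32 to -0.22 without 1 sample), and Cd83 by 1.95, where Auto.Neg sample 1 read 4.06 and the other 7 samples 7.71 to 8.68. Macrophage and monocyte markers lay higher for 12 of 17 genes (median 0.17, camera adjusted p = 0.0564), with a negative median on slide 2 and in the submitters' table read by its labels (-0.36). With the protocol block this list passed, shifted up (camera adjusted p = 0.0194). Survival and death regulators had a median of -0.07 (camera adjusted p = 0.566), with the pro-death gene Bmf at -1.04 (0.03 on another probe) and the survival kinase gene Pim2 at -0.75. Follicular B cell and homing genes had a median of 0.10 that turned to -0.04 under median centring (camera adjusted p = 0.669), with the transcription factor gene Foxp1 at 0.65 and the cytokine receptor gene Il4ra at -0.59 (-1.06 to -0.12 without 1 sample). B-1 cell markers had a median of 0.16 that turned to -0.20 in the submitters' table (camera adjusted p = 0.719), with the phosphatase gene Ptpn22 at 1.07 and Zcwpw1 at -1.03 (-0.39 on another probe). The median was -0.04 for inhibitors of receptor signalling. It was -0.05 for B cell receptor complex genes, -0.06 for MYC-related genes, -0.01 for Toll-like receptor signalling (mean 0.01, camera up) and -0.10 for the cell cycle, each changing sign under at least 1 scaling alternative.

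Median centring moved the median difference of all genes from 0.02 to -0.07, scale normalization left it at 0.02, and it was -0.16 in the submitters' table. Heat shock genes had a median of 0.06, transitional B cell markers 0.03, genes near Thy1 0.04, plasma cell markers 0.06 (mean -0.02, camera up) and antigen presentation genes 0.01 (mean -0.11, camera down), each changing sign under at least 1 scaling alternative. Of markers of other cell types, T cell markers had a median of 0.08 (camera down), NK cell markers -0.04, dendritic cell markers 0.08, erythroid and platelet markers 0.06 and neutrophil markers 0.01 (mean -0.09, camera down), all but the NK list changing sign under at least 1 scaling alternative. Each list that did not pass camera had 0 genes called over all genes and, apart from Nod1, 0 adjusted over the list alone, with camera adjusted p from 0.0513 to 0.994.

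The name rule caught only 3 immunoglobulin units because the array names most of them by clone. A wider rule on symbols and descriptions, written after the names were seen, gave 109 units, of which 52 were kappa or other light chain and 52 heavy chain. Between Auto.Pos and Auto.Neg the kappa and light chain units had a median difference of -0.30 (slide 2 -0.43), with 16 higher and 36 lower, 3 called over all genes and 13 adjusted over the list alone. The camera adjusted p was 1.21e-13 and the adjusted p = 0.506 with an estimated correlation. The heavy chain units had a median of -0.08, with 20 higher and 32 lower, and 0 of them were 2-fold apart, whereas 3 light chain units were 2-fold higher and 11 lower. In the submitters' table read by its labels the light and heavy chain medians were 1.21 and 2.03. There the columns labelled Auto.Pos sample 1 match WT sample 1.

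The comparison of Auto.Pos with WT cells asks how B cells of the transgenic autoreactive specificity differ from a normal follicular population. Immunoglobulin variable gene units lay far lower in Auto.Pos, for heavy and light chains alike. Auto.Pos cells carry a given heavy and light chain transgene and WT cells do not. Lower values of other units can thus follow from how the mice were made and cannot be read as an effect of autoreactivity. Nod1 lay 2.67-fold higher and Cd9 3.98-fold higher in Auto.Pos than in WT. Antigen presentation genes shifted down as a list at the preset correlation, but not with an estimated correlation (adjusted p = 0.86). Tapbp, which loads peptides on class I molecules, passed adjusted over the list alone, with 0.30 on another probe. The T cell kinase gene Lck, also expressed in some B cells, lay lower.

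limma called 0 of 20469 genes between Auto.Pos and WT, with 1152 at an unadjusted p under 0.05, 13 at an adjusted p under 0.1 and a lowest adjusted p of 0.0902. With the protocol block 2201 genes had an unadjusted p under 0.05, and 0 were called. Of the 1152 genes 85 were immunoglobulin by the wider rule, as were 11 of the 13. Of the 109 wider immunoglobulin units, 102 lay lower and 7 higher, with a median of -2.29 and -1.71 inside scan day 3. In the submitters' table read by its labels their median was 0.34. There the columns labelled Auto.Pos sample 1 match WT sample 1, so this value does not compare the 2 groups. Of these units 0 were called over all genes and 84 adjusted over the list alone, with a camera adjusted p of 3.81e-98 and adjusted p = 0.0312 with an estimated correlation. The light chain median was -2.24 (50 of 52 lower, 37 of them 2-fold) and the heavy chain median -2.47 (47 of 52 lower, 40 of them 2-fold), with adjusted p = 0.0312 and 0.0379 with an estimated correlation. Igk-V1, a kappa variable gene on the list of the name rule, differed by -3.62 (limma adjusted p = 0.00139 adjusted over the list alone).

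**Figure D3:**
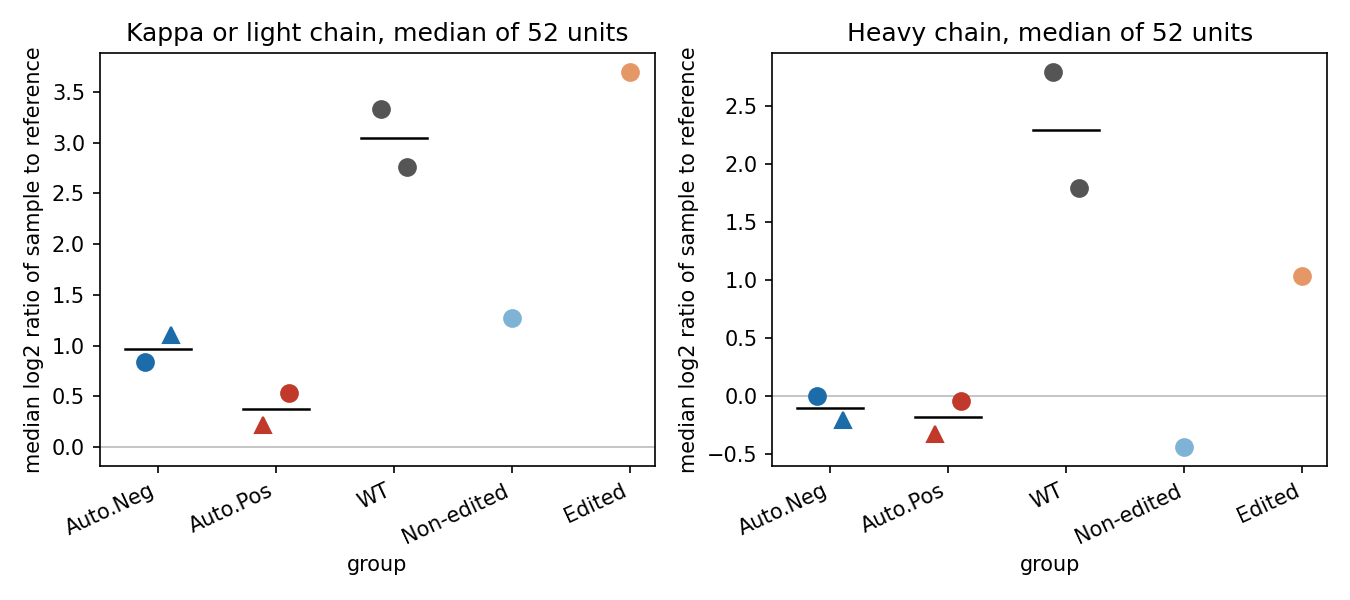
Median log2 ratio of sample over reference across 52 kappa or light chain units (left) and 52 heavy chain units (right), with 1 point per biological sample, triangles for the samples of slide 2 and a line at each group mean. The light chain medians are 3.33 and 2.75 in WT, 0.84 and 1.102 in Auto.Neg and 0.22 and 0.53 in Auto.Pos. They are 1.27 in Non-edited and 3.70 in Edited. In the submitters' table read by its labels the Auto.Pos minus WT medians turn positive (0.14 light, 0.41 heavy). There the columns labelled Auto.Pos sample 1 match WT sample 1.

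Nod1 differed from WT by 1.42 (SE 0.263, limma adjusted p = 0.4), with 1.42 inside scan day 3 and an adjusted p of 0.179 with the protocol block and of 0.088 to 1.00 over all alternatives. Under scale normalization the Nod1 difference was 0.453. Nod2 differed by -1.07 (SE 0.320, limma adjusted p = 0.723; scan day 3 -0.77) and Ripk2 by -0.08 (SE 0.403, scan day 3 0.55), where 2 of 4 WT arrays were well above background. Thy1 differed by 0.45 on its brighter probe and by -0.01 on the other. The NOD and inflammasome list had 9 genes higher and 13 lower (median -0.05, turning to 0.10 in the submitters' table, camera adjusted p = 0.273), with 0 called over all genes and 0 adjusted over the list alone, and Slc15a3 at -1.23. Antigen presentation genes lay lower for 11 of 17 genes (median -0.26, scan day 3 -0.28, -0.0357 as the weakest without 1 sample, camera adjusted p = 0.0189), and adjusted p = 0.86 with an estimated correlation. Of them 0 were called over all genes and 1, Tapbp, adjusted over the list alone at -1.04 (SE 0.187, scan day 3 -1.01, 0.30 on another probe). The peptide transporter gene Tap1 differed by -1.08 (scan day 3 0.60), and in the submitters' table read by its labels camera's direction for the list turned. Lck differed by -1.30 (SE 0.194, limma adjusted p = 0.0165 adjusted over the list alone) and Cd9 by 1.99 (0.00784 adjusted over the list alone; 0.81 on another probe).

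Of 86 higher and 126 lower genes at least 2-fold apart in all 4 pairs at an unadjusted p under 0.05, 44 and 23 had gene names and were not immunoglobulin. The highest were the basement membrane gene Nid1 (2.86, scan day 3 4.26), Ankrd33b (2.81, scan day 3 3.35; 0.34 on another probe), the receptor kinase gene Grk3 (2.57, scan day 3 2.23; -0.02 on another probe) and Pgpep1l (2.32, scan day 3 1.97). Lysmd2 (2.27, scan day 3 2.82), the calcium-binding gene Rcn3 (2.21, scan day 3 2.46; 2.18 on another probe), Sh3bgrl2 (2.07, scan day 3 1.05; 3 of 4 WT arrays above background) and the helicase gene Dhx40 (2.06, scan day 3 2.39) followed. The lowest were Eif2s3y (-6.09, limma adjusted p = 0.0902), the calmodulin-binding gene Pcp4 (-2.94, scan day 3 -4.24; -0.97 on another probe), the Ral exchange factor gene Rgl1 (-2.90, scan day 3 -4.12; -0.92 on another probe) and the stress-response gene Ndrg1 (-2.79, scan day 3 -3.76). Cpne4 (-2.24, scan day 3 -1.96), Ccdc186 (-2.05, scan day 3 -1.43; -0.25 on another probe), the acyltransferase gene Gpat3 (-2.03, scan day 3 -1.73) and Dmwd (-2.03, scan day 3 -2.03) followed. Without 1 sample Nid1 ran from 1.58 to 4.15, Sh3bgrl2 from 1.15 to 2.99 and Pcp4 from -4.16 to -1.72. Groups did not overlap for 6054 genes (29.6%), against 33.3% by chance if all samples were exchangeable. The deviations of Auto.Pos sample 1 and WT sample 1 correlated at 0.252, so this condition was not met.

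Median centring moved the median of all genes from 0.06 to -0.06 here. In the other lists of this comparison 0 genes were called over all genes, and camera adjusted p ran from 0.0621 for the sex-linked list to 0.989. Further genes passed adjusted over the list alone only in the T cell list (1, Lck), the marginal zone list (1, Cd9), the sex-linked list (1, Eif2s3y) and the immunoglobulin name rule (1, Igk-V1). B-1 markers had a median of 0.05 (-0.16 under median centring), with Ptpn22 at 1.37 and the annexin gene Anxa2 at -0.67. Activation-induced genes had a median of -0.01, with Ccnd2, a cyclin induced on activation, at -1.30 and Dusp1 at 0.79. Follicular and homing genes had a median of 0.00 (-0.13 under median centring), with the chemokine receptor gene Cxcr4 at 1.17 and the egress receptor gene S1pr1 at -0.97. Survival regulators had a median of -0.09 (mean 0.05), with Pim1 at 1.89 (0.69 to 3.10 without 1 sample; 0.17 on another probe) and Bmf at -1.25 (0.17 on another probe), and NF-kB genes one of -0.00 (mean 0.01), with Nfkbiz at 0.74 (0.17 to 1.30 without 1 sample) and Chuk at 0.63 (0.20 on another probe). Interferon response genes had a median of -0.06, macrophage markers -0.29 (0.35 in the submitters' table read by its labels), erythroid markers -0.32 (mean 0.04) and neutrophil markers -0.21.

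The comparison of Auto.Neg with WT cells asks what the transgenic receptor changes where its antigen is absent. Immunoglobulin units lay far lower in Auto.Neg as well, which can likewise follow from the given transgenic chains. At the preset correlation marginal zone B cell markers, macrophage markers and the NOD and inflammasome list shifted down as lists. With an estimated correlation none of these shifts passed (adjusted p = 0.632, 0.929 and 0.632, in this order). Sdc1, the syndecan of plasma cells, and Cd24a, high on immature B cells, lay lower, while the Wnt pathway transcription factor gene Lef1 lay higher.

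limma called 0 of 20469 genes between Auto.Neg and WT, with 941 at an unadjusted p under 0.05 and a lowest adjusted p of 0.146. With the protocol block 2018 genes had an unadjusted p under 0.05, and 0 were called. Of the 109 wider immunoglobulin units 96 lay lower and 13 higher (median -2.13), with 0 called over all genes and 88 adjusted over the list alone. Their camera adjusted p was 2.26e-79, and the adjusted p = 0.0406 with an estimated correlation. The light chain median was -1.48 (45 of 52 lower) and the heavy chain median -2.52 (46 of 52 lower), each with adjusted p = 0.0406 and an estimated correlation. All medians of these units stayed negative under the scaling alternatives. They were negative in the submitters' table read by its labels too. There the columns labelled WT sample 2 match Auto.Neg sample 1, so these values do not compare the groups. Igk-V1 differed by -2.66 (limma adjusted p = 0.00591 adjusted over the list alone). Of the 109 units, 0 lay near background on all arrays of WT, against 11 in Auto.Neg, 25 in Auto.Pos, 33 in Non-edited and 3 in Edited.

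Marginal zone markers lay lower for 11 of 15 genes (median -0.41, camera adjusted p = 0.00482; without 1 sample -0.41 to -0.14 with up to 0.0569), with Tm6sf1 at -1.66 and the sphingosine receptor gene S1pr3 at -1.30 (-0.11 on another probe), and adjusted p = 0.632 with an estimated correlation. Macrophage and monocyte markers lay lower for 15 of 17 genes (median -0.46, 0.0366 without Auto.Neg sample 1, camera adjusted p = 0.00482), with the lysozyme gene Lyz2 at -1.24 (-0.24 on another probe) and Spic at 1.16 (0.126 to 2.19 without 1 sample), and adjusted p = 0.929 with an estimated correlation. In the submitters' table read by its labels the macrophage median was 0.80 and the marginal zone median 0.12. The NOD and inflammasome list lay lower for 16 of 22 genes (median -0.14, camera adjusted p = 0.0267; without 1 sample -0.33 to -0.11 with up to 0.224), with the transporter gene Slc15a4 at -0.77, and adjusted p = 0.632 with an estimated correlation. Each of these 3 lists had 0 genes called over all genes and 0 adjusted over the list alone. Nod1 differed by -0.78 (SE 0.263, limma adjusted p = 1.00; -1.31 under scale normalization), Nod2 by -0.48 (SE 0.320) and Ripk2 by -0.12 (SE 0.403). Thy1 differed by 0.33 on its brighter probe and by 3.30 on the other.

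Of 93 higher and 106 lower genes at least 2-fold apart in all 4 pairs at an unadjusted p under 0.05, 49 and 15 had gene names and were not immunoglobulin. The highest were the kinase gene Taok1 (3.48; 0.03 on another probe), Pigt, which attaches membrane anchors (3.44; 0.15 on another probe), Dscam (2.73; 3 of 4 WT arrays above background; -0.03 on another probe), the roquin family gene Rc3h2 (2.72; 0.61 on another probe) and Ptchd1 (2.72; 3 of 4 WT arrays above background). Snx27 (2.45; -0.55 on another probe), Pgpep1l (2.44) and Lef1 (2.28; 1.72 on another probe) followed. The lowest were Jhy (-4.05; -1.27 on another probe), the deubiquitinase gene Usp2 (-2.95, SE 0.424, limma adjusted p = 0.281), Gpat3 (-2.19; -1.81 on another probe), Phxr2 (-2.02; 2 of 4 Auto.Neg arrays above background) and the glucan receptor gene Clec7a (-2.00). Ccdc186 (-1.86; -0.21 on another probe), Sdc1 (-1.77) and the ribosome assembly gene Mdn1 (-1.69; -0.32 on another probe) followed. Groups did not overlap for 5109 genes (24.96%), against 33.3% by chance if all samples were exchangeable. The deviations of Auto.Neg sample 2 and WT sample 1 correlated at 0.279, so this condition was not met.

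In the other lists 0 genes were called over all genes, and camera adjusted p ran from 0.088 to 0.985. Sdc1 passed adjusted over the list alone (1 gene, SE 0.270, limma adjusted p = 0.0149), as did 2 genes of the transitional B cell list, Lef1 and Cd24a (-0.99), each with a limma adjusted p = 0.0366, and Igk-V1 of the name rule. NF-kB genes had a median of 0.09 (-0.18 under scale normalization), with the inhibitor gene Nfkbia at 0.65 and Birc3 at 0.57. Activation-induced genes had one of 0.15, with Junb at 0.95 (0.232 to 1.67 without 1 sample) and Cd83 at -2.09, the latter resting on Auto.Neg sample 1 and 0.05 without it. Follicular and homing genes had a median of -0.16 (0.25 in the submitters' table read by its labels), with Cxcr4 2.29-fold higher and S1pr1 at -1.15. Survival regulators had a median of 0.10 (-0.02 under median centring, camera down), with the pro-death gene Bbc3 at 1.88 (0.904 to 2.85 without 1 sample) and Pim1 at 1.31 (0.105 to 2.51 without 1 sample; 0.09 on another probe). B-1 markers had one of -0.12, with Zcwpw1 at 0.88 (-0.52 on another probe) and Ahnak at -0.69 (0.16 on another probe).

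The comparison of Edited with Non-edited cells asks what differs between cells of the same transgenic background with and without receptor editing. Nod1 lay 5.53-fold higher and Cd9 5.70-fold higher in the Edited sample. Immunoglobulin units lay higher in the Edited sample for both chain types. Marginal zone and B-1 markers lay higher, and cell cycle, heat shock and transitional B cell genes lay lower. With 1 sample per group the dye-swap arrays are the only repeat. limma with the spread of the replicated groups called 0 of 20469 genes, with 241 at an unadjusted p under 0.05, so the differences are values without a passed test.

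At least 2-fold differences in both dye orientations were seen for 284 genes, 249 higher and 35 lower in Edited, and the orientations correlated at 0.773 across genes. Of these, 58 higher and 4 lower genes were immunoglobulin by the wider rule, 61 more had clone names only, and 137 higher and 24 lower genes had names. Nod1 read 1.60 in Non-edited and 4.07 in Edited, a difference of 2.47 (2.36 with the sample in Cy5, 2.58 in Cy3). The highest named genes were the neuropilin receptor gene Nrp2 (2.91), the cold-induced RNA-binding gene Cirbp (2.89), Lmo7 (2.53; 0.04 on another probe), Cd9 (2.51; 0.29 on another probe), the transcription factor gene Tbx21 (2.49) and Nod1. The lowest were the antimicrobial peptide gene Camp (-2.64; 1 of 2 Edited arrays above background), the heat shock gene Hsph1 (-2.20) and Ntng1, at least 4.52-fold lower since it was not well above background in Edited. Pde2a (-1.92; -1.71 on another probe), the lactoferrin gene Ltf (at least 4.62-fold lower; -0.85 on another probe) and the opioid peptide gene Penk (-1.64) followed. Nod2 differed by -0.04 and Ripk2 by 0.05.

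List medians were set against 10000 random lists of equal size matched on signal, as a description of these 2 samples. B-1 markers had a median of 0.71 (percentile 100), with Ptpn22 at 1.99, Ahnak at 1.60 (0.43 on another probe) and Cd300lf at 1.23 (-0.13 on another probe). Marginal zone markers had a median of 0.50 (percentile 100), with Cd9, Myof at 1.59 and S1pr3 at 1.24. Macrophage markers had a median of 0.19 (percentile 99.7), with Adgre1 and Spic each at 1.49, and the NOD list had one of 0.10 (percentile 97.0), with the inflammatory caspase gene Casp4 at 1.53 and Naip5 at 1.36. Wider immunoglobulin units had a median of 1.41 (percentile 100; light chain 1.46, heavy chain 1.45), and the name rule one of 0.34 (percentile 97.2). Heat shock genes had a median of -0.59 (percentile 0), transitional B cell markers -0.45 (percentile 0), neutrophil markers -0.42 (percentile 0), cell cycle genes -0.35 (percentile 0) and T cell markers -0.35 (percentile 0.04). Lck lay at 1.86 and the neutrophil gene Mpo at 1.62 against their lists. These 11 list medians kept their sign under median centring, scale normalization, the scanner software's ratios and the submitters' table.

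The remaining medians lay between -0.14 and 0.11. Activation-induced genes had a median of 0.07 (percentile 92.3), with the early response genes Egr3 at 1.68 (0.05 on another probe) and Egr2 at 1.54. Survival regulators had a median of -0.00 (percentile 63.8), with Pmaip1 at 2.24, Bcl2 at 1.54 (0.08 on another probe) and Bcl2a1b at 1.23. Inhibitors of receptor signalling had a median of -0.06 (percentile 33.5), with Fcrl5 at 1.72 (0.62 on another probe) and Nt5e at 1.62. The median was -0.14 for follicular genes (percentile 5.34), -0.14 for erythroid markers (percentile 7.73, Car2 2.14-fold higher), 0.11 for plasma cell markers (percentile 88.6, Xbp1 -1.03) and 0.09 for antigen presentation (percentile 90.7). It was 0.07 for MYC-related genes (percentile 86.2), 0.03 for Toll-like receptor signalling (percentile 78.1), -0.03 for the receptor complex (percentile 39.4), -0.06 for NF-kB genes (percentile 28.0) and -0.05 for the interferon response (percentile 47.5). NK cell, dendritic cell and germinal centre markers had -0.07, -0.04 and -0.04, sex-linked genes -0.09 and genes near Thy1 -0.02 (percentile 62.4), the latter with Arhgef12 at 1.70 (0.37 on another probe), 1810046K07Rik at 1.48 and Zc3h12c at 1.43. Of these, the follicular, erythroid, survival, receptor complex, inhibitor, NF-kB, interferon, dendritic, germinal centre and near-Thy1 medians turned under median centring, which moved the median of all genes from -0.03 to 0.10. The Toll-like receptor median turned with the scanner software's ratios and the sex-linked one in the submitters' table.

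The 3 genes called lower in Auto.Pos than in Auto.Neg had a median difference of -1.55 in Edited against Non-edited (percentile 0), with 3 of 3 lower. All 3 are kappa units that read higher in the samples with the transgenic light chain of Auto.Neg than in WT. Editing is the replacement of a receptor chain, so lower values of these units in Edited can follow from how these samples were defined. The random lists were not limited to kappa units, so percentile 0 cannot show a difference shared with Auto.Pos. As 0 genes were called higher in Auto.Pos, no higher set was followed. With the protocol block 3 genes were called higher beside the 3 lower ones.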

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

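Most alternatives were fixed before the data were examined, and the rematched series table, the scanner block, the fit without slide 2 and the wider immunoglobulin lists were chosen after it. There were 32 alternative settings over all main results, and not every setting applied to every result. The cause of a change was not tested unless named.

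The 3 genes called between Auto.Pos and Auto.Neg became 1 under median centring, 7 with 16 arrays and biological sample as random block (array correlation 0.759), 6 with the protocol block and 12 with the sample in Cy5 only, of which 1, 3 and 3 were higher in Auto.Pos. They became 0 with scale normalization, the series table as labelled, no filter on dim probes, variance trend and robust fitting, only the 2 groups compared, the scanner block, without both samples of slide 2 and with the sample in Cy3 only (limma, 200, 2113, 365, 177, 239, 588, 290 and 224 genes at an unadjusted p under 0.05, in this order). Without 1 sample, where the lone sample left is assumed to vary like the other groups, the count ran from 0 to 0, and every omission lost the calls. On slide 2, 3 of 3 called genes kept their direction. The replicate block by sample number gave 0 calls (limma, 130 at an unadjusted p under 0.05). The deviations of samples numbered 1 correlated at -0.788 between Auto.Neg and Auto.Pos. Auto.Neg sample 2 and Auto.Pos sample 1 shared slide 2, so this value cannot show whether the numbers pair samples.

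The 0 calls between Auto.Pos and WT became 15 with the scanner software's log ratios, 14 with the rematched table, 155 with 16 arrays, 72 in Cy5 only and 13 at an adjusted p under 0.1. The 0 calls between Auto.Neg and WT became 1 with the rematched table, 86 with 16 arrays and 60 in Cy5 only. Without 1 sample both stayed at 0. The 16-array fit counts dye-swap arrays as samples in part. The 284 genes of Edited against Non-edited became 808 with the scanner software's log ratios, 100 at 3-fold and 0 by limma on the pooled spread (241 at an unadjusted p under 0.05). The median of the Auto.Pos genes in Edited, -1.55, became -1.22 with the scanner software's log ratios and -0.44 under median centring, where 1 gene was called in place of 3, and had no value where no gene was called.

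Nod1 in Auto.Pos against Auto.Neg was 2.20 with 16 arrays at adjusted p = 0.0453, against 0.485 and a range of 0.0453 to 1.00 over all alternatives, and ran from 2.02 to 2.39 without 1 sample. It was 0.147 (adjusted p = 0.917) in the table as labelled and 1.76 under scale normalization. Nod1 in Auto.Pos against WT was 0.453 under scale normalization. Nod1 in Auto.Neg against WT turned to 1.01 in the table as labelled, was -1.31 under scale normalization and ran from -0.97 to -0.60 without 1 sample.

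The 6 lists shifted between Auto.Pos and Auto.Neg became 0 in the table as labelled and 0 with an estimated correlation, and 0 to 5 without 1 sample (2 without Auto.Neg 1, 1 without Auto.Pos 1, 0 without Auto.Pos 2). The 1 list between Auto.Pos and WT became 0 with the scanner software's log ratios, 13 with scale normalization, 5 in the table as labelled, 3 with the mean of probes, 3 with the replicate block, 2 with the scanner block, 4 without slide 2 and 0 with an estimated correlation, and 0 to 3 without 1 sample (3 without Auto.Pos 1, 0 without Auto.Pos 2, 2 without WT 1). The 3 lists between Auto.Neg and WT became 1 with the scanner software's log ratios, 9 with scale normalization and 0 with an estimated correlation, and 1 to 8 without 1 sample (1 without WT 1, 8 without WT 2).

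In the series table as labelled, whose columns follow another order than the arrays, these differences reversed. For Auto.Pos against Auto.Neg: Alox12 -0.24, Cd83 -0.25, Ctla2a -1.69, Ctla2b -1.70, Il4ra 0.73, Myl9 -1.69, Nod2 0.57, Ptpn22 -0.66, Slamf1 0.0709, Thy1 -0.27, and by camera's direction the NF-kB (-0.14), immunoglobulin (-0.18) and interferon (-0.12) lists. For Auto.Pos against WT: Bmf 0.23, Ccdc186 0.45, Chuk -0.0674, Cpne4 0.21, Gpat3 0.16, Nfkbiz -0.48, Pgpep1l -0.12, Ripk2 0.17, S1pr1 0.41 and antigen presentation (-0.0627). For Auto.Neg against WT: Ahnak 1.45, Cd83 2.26, Jhy 0.95, Lyz2 0.83, Zcwpw1 -0.60 and macrophage markers (0.80).

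Scale normalization reversed Anxa2 in Auto.Pos against WT (0.0166) and, in Auto.Neg against WT, Birc3 (-0.12) and Ddx3y (-0.28). Cy3 alone reversed Cd83 (0.0436 in Auto.Neg against WT, -0.35 in Auto.Pos against Auto.Neg) and Ripk2 in Auto.Pos against WT (0.0389), and Cy5 alone Ddx3y (-0.18). The scanner block reversed Ddx3y (-1.79), Ripk2 (0.27 in Auto.Neg and 0.31 in Auto.Pos, against WT) and Tap1 (0.58). Ripk2 also reversed with the scanner software's log ratios (0.10 and 0.14), the rematched table (0.0401 in Auto.Neg against WT, -0.13 in Auto.Pos against Auto.Neg) and without background subtraction (0.0266). Thy1 in Auto.Pos against Auto.Neg reversed with the mean of probes (-1.59) and median centring (-0.00436). Without slide 2 Ddx3y (-0.40), Rgs13 (0.0788), Ripk2 (0.20 in Auto.Neg and 0.38 in Auto.Pos, against WT), Tap1 (0.77) and Thy1 (-0.22) reversed.

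Without 1 sample these reversed, with the omitted samples in brackets. For Auto.Neg against WT: Ahnak -1.53 to 0.15 (Auto.Neg 1, WT 1), Cd83 -4.23 to 0.0502 (Auto.Neg 1), Ddx3y -0.40 to 0.58 (Auto.Neg 2, WT 1) and Ripk2 -0.44 to 0.20 (Auto.Neg 2, WT 1). For Auto.Pos against Auto.Neg: Cd83 -0.19 to 4.09 (Auto.Neg 1), Chuk -0.40 to 1.42 (Auto.Neg 2, Auto.Pos 2), Rgs13 -0.98 to 0.0417 (Auto.Pos 1), Ripk2 -0.41 to 0.50 (Auto.Neg 2, Auto.Pos 2), Thy1 -0.13 to 0.37 (Auto.Pos 1), Xist -0.0720 to 9.03 (Auto.Pos 2) and the interferon list -0.88 to 0.29 (Auto.Neg 1). For Auto.Pos against WT: Chuk -0.28 to 1.54 (Auto.Pos 2), Ripk2 -0.53 to 0.38 (Auto.Pos 1, WT 1) and Tap1 -2.92 to 0.77 (Auto.Pos 1). List medians also turned sign without passing camera for marginal zone markers in Auto.Pos against Auto.Neg, -0.0766 to 0.49 (Auto.Pos 1), and macrophage markers in Auto.Neg against WT, -1.09 to 0.0366 (Auto.Neg 1).

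Without 1 sample these kept their sign but fell under 50% of their value at the weakest. For Auto.Pos against Auto.Neg: Nod2 -1.005 to -0.18, Traf1 -1.01 to -0.32, Egr2 -1.32 to -0.22, Il4ra -1.06 to -0.12, Tm6sf1 0.27 to 1.23, Stat2 -1.45 to -0.25 and Myl9 1.14 to 3.81. For Auto.Pos against WT: Thy1 0.21 to 0.70, Anxa2 -1.08 to -0.26, Nfkbiz 0.17 to 1.30, S1pr1 -1.46 to -0.49, Xist 0.38 to 9.48, Pim1 0.69 to 3.10 and Bmf -1.93 to -0.58. For Auto.Neg against WT: Zcwpw1 0.30 to 1.46, Junb 0.23 to 1.67, Lyz2 -1.92 to -0.55, Spic 0.126 to 2.19, Bbc3 0.90 to 2.85 and Pim1 0.105 to 2.51.

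Of the tested gene results, 2626 stayed the same, 67 reversed, 47 were weaker and 24 stronger. For these, the same means only that the sign and the side of the threshold were kept, whatever the size. As nearly all named genes were uncalled, these counts do not measure how stable the sizes were. Of the untested gene results 437 stayed and 26 moved. Of the list results 135 stayed, 68 were weaker and 6 reversed. These counts include the submitters' table read by its labels, whose columns mix the groups. It gave every list reversal except that of the interferon list without Auto.Neg sample 1, and part of the gene reversals. Signal over background limits Xist, Ripk2, Eif2s3y, Loxhd1, Phxr2 and the dim immunoglobulin units, where some arrays of a group lie near background. Slide as a random block was not run, since 7 slides held 8 samples.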

Other observations

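Only the 3 tests on slide 2 were written before their results were seen, and the tests on Nod1, on the Thy1 probe and on the ranked genes were chosen only after the result was seen.

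Sex-linked genes differed within the Auto.Pos group. Xist, the RNA that silences an X chromosome in females, read 0.02 and 9.12 in the Auto.Pos samples, 0.16 and 0.02 in Auto.Neg, -0.57 and -0.14 in WT, 9.80 in Non-edited and 10.12 in Edited. The Y-linked gene Ddx3y read 2.69 and -3.86 in Auto.Pos, 1.36 and 2.34 in Auto.Neg, 1.54 and 1.97 in WT, -3.67 in Non-edited and -4.27 in Edited. Kdm5d, a Y-linked demethylase gene, read 2.06 and -2.58 in Auto.Pos, 2.22 and 1.89 in Auto.Neg, 1.57 and 2.44 in WT, -2.52 in Non-edited and -2.82 in Edited. Eif2s3y, a Y-linked translation factor gene, read 0.89 and 0.15 in Auto.Pos, 6.48 and 6.59 in Auto.Neg, 7.25 and 5.96 in WT, -0.10 in Non-edited and 0.03 in Edited. Auto.Pos sample 1 thus carried Ddx3y and Kdm5d at the level of the Auto.Neg and WT samples, with Eif2s3y near that of the samples high in Xist. The samples compared thus differed in sex-linked expression, Auto.Pos sample 2, Non-edited and Edited being high in Xist and the others low, and whether a sample was pooled or exchanged was not tested.

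Samples also resembled each other across groups apart from slide 2. Auto.Neg sample 1 and Non-edited correlated at 0.976 across genes, and Edited and Non-edited at 0.974. These 3 samples shared scan day 4, scanner and protocol, on different slides. By the labels they also shared the VH3609 and Vk21-5 transgenes and the Thy-1 knockout. Auto.Neg sample 2, with the same transgenes and knockout but on slide 2, correlated at 0.896 with Non-edited. Auto.Pos sample 2, with another transgenic light chain and scan day, correlated at 0.957 with Auto.Neg sample 1, 0.958 with Non-edited and 0.952 with Edited. Its correlation with Auto.Pos sample 1 was lower, at 0.904. By scanner and protocol Auto.Pos sample 2 was like the samples of scan day 4.

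Nod1 lay 2.20 higher in Auto.Pos than in Auto.Neg, and technical causes were weighed. A slide or scanner effect was excluded as the sole cause by the difference of 2.22 on slide 2, which held both groups. The lower single-dye difference was 2.11, so the difference did not rest on a single dye orientation. A dye bias of the probe common to all arrays would cancel between groups labelled alike, so this value does not test it. A sequence difference under the probe could not be told apart, since Nod1 had 1 probe. The order of the submitters' table, by which the difference was 0.147, was excluded as the right one, since it gave 1 sample 2 columns that differed by 6.06 in the called kappa units. No test decided the biological explanation, that the antigen-binding group carries more Nod1. WT lay between the groups, with Auto.Pos 1.42 above it (0.453 under scale normalization) and Auto.Neg at -0.78. Nod1 also read 1.60 in Non-edited and 4.07 in Edited (1 sample each), both from Thy-1 knockout mice. A Nod1 difference thus also appeared between samples that both lacked Thy-1.

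The samples of slide 2 correlated at 0.978, above both within-group correlations by 0.0741. Over probes well above background on all 16 arrays the gap was 0.0751, so dim probes were excluded as its cause. The lower single-dye gap was 0.0697, so the gap did not rest on a single dye orientation. A dye bias shared by the arrays of slide 2 would remain within each orientation, so this value cannot exclude it. Scanner, hybridisation or RNA preparation of that slide could not be told apart, since 0 samples on that scanner lay outside the slide. No biological explanation was tested, as the samples belong to different groups.

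The second Thy1 probe read higher in the 4 knockout samples (mean -0.51, lowest -1.43) than in the other 4 (mean -3.35, highest -2.93). T cells in the samples were excluded as the cause, since the median of 15 other T cell markers was -0.11 in the knockout samples minus the rest. A slide or scanner effect was excluded by the difference of 3.39 on slide 2. A transcript from the targeted allele is a candidate explanation, which these tests (-0.11 and 3.39) leave open and the position of the deletion would decide.

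The 100 genes of smallest p in each direction of Auto.Pos over Auto.Neg, without immunoglobulin units, were followed into Edited against Non-edited to test whether these samples differ alike. The higher set had a median of 0.17 over 99 measured genes (63 higher, 36 lower, percentile 100) and the lower set one of -0.00 (50 higher, 50 lower, percentile 83.5). The lower set thus showed no shift in the same direction, while the higher set alone was shifted the same way. Only 213 of 20469 genes had an unadjusted p under 0.05 by limma between Auto.Pos and Auto.Neg, so the ranked genes may be largely noise. The lower set therefore cannot decide whether a difference is shared.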
